A study of Coturnix japonica with 20 samples.

How the data were processed

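Left-lobe liver of 20 Japanese quail (Coturnix japonica) embryos was profiled by RNA sequencing at embryonic day 9. Per the labels' protocols, eggs received 10 µl of dosing solution in the air cell before incubation at 37 °C and 60% humidity, RNA was extracted on silica columns with an added DNase digestion, and libraries followed standard Illumina procedures. Sex and treatment came from the labels, which gave 5 male and 5 female embryos with solvent and 4 male and 6 female embryos with ethinylestradiol. Nothing in the sources used here says how embryos were sexed or whether they shared a parent, so p values measure the spread between these embryos as labelled. No sequencing batch or date was given in the sources used here.

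The authors deposited 2 tables of estimated counts per coding sequence, with 40934 coding sequences in each, made with kallisto per the submitters' processing notes. The version, the transcript set and the genome build were not given in the sources used here. kallisto assigns a read that fits several transcripts in fractions, so that 52.64% of the deposited values were exact whole numbers and the rest were fractions. Estimates for genes with near-identical copies are therefore uncertain, and this includes the loci without a gene name described in the results, for which the sharing of reads was not tested. Both tables held identical values for all 40934 coding sequences and differed in the identifier. The table carrying NCBI gene identifiers served as the main source, and the other served as an alternative, in which 40894 entries could be matched to a gene by protein.

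Estimated counts were summed over the coding sequences of a gene and rounded to whole numbers, giving 16066 genes. All 16066 identifiers matched a gene table of the NCBI assembly Coturnix japonica 2.1, which was used for gene names and for membership of the Z chromosome. Because the build behind the deposited counts was not stated, no coordinates are given. Of the 16066 genes, 3043 carried only a locus symbol, that is LOC followed by the gene identifier. Total estimated counts per library ranged from 15298506 to 32119466. The edgeR function filterByExpr with its minimum count of 10 and minimum total of 15 removed 2565 genes and kept 99.9837% of the counts. Of the 13501 genes tested, 11535 had a name, 1966 had only a locus symbol and 601 lay on Z. Libraries of a group were compared before averaging. No 2 libraries were identical, and the lowest chi-square per gene between libraries of a group was 31.64, far above sampling noise, so all 20 were kept as separate samples.

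Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling and the robust quasi-likelihood test (two-sided). All 20 libraries entered 1 fit with a mean for each group, and the biological coefficient of variation was 0.245. The 6 comparisons were the effect of ethinylestradiol in males, in females and averaged over the sexes with equal weight, the difference between the female and male effects (the interaction), and the difference between the sexes in solvent and in ethinylestradiol embryos. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Log2 fold changes are edgeR estimates. Standard errors (SE) were derived from each fold change and its F statistic. Levels are CPM, the usual depth-scaled count, on TMM-scaled library sizes, given as mean ± SD. For a gene with 1 to 3 counts in a whole solvent group, the ratio is given with a 95% interval, which covers counting error only, since reads are not independent molecules. The male and female comparisons share no control library.

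Gene lists were fixed before the data were examined, as were the comparisons, tests and alternatives except those named as later additions. The 17 pathway lists covered egg yolk precursors and other estrogen-induced secretory genes, estrogen receptors and coregulators, steroid synthesis and inactivation, bile acids, cholesterol, fatty acid and triglyceride synthesis, fatty acid oxidation, xenobiotic metabolism, the thyroid hormone axis, oxidative stress defence, endoplasmic reticulum stress and folding, the cell cycle, coagulation with complement and acute phase, the interferon and inflammatory response, glucose metabolism, extracellular matrix, and gonadal sex determination. The 10 marker lists covered hepatocytes, cholangiocytes, erythroid cells, macrophages, endothelium, stellate and other mesenchymal cells, granulocytes and lymphoid cells, mesonephros and kidney, striated muscle, and mesothelium. Lists with at least 3 tested members were tested with limma 3.58.1 (camera on voom values with a preset correlation of 0.01, adjusted over lists within a comparison), beside camera with an estimated correlation and fry. The mesothelium list had 1 tested member and was not tested. Calls on list members are given over all genes tested and adjusted over the list alone.

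Named genes followed a rule: in each comparison, the 10 highest and 10 lowest fold changes among called genes with a mean log2 CPM of at least 1, up to 4 called members of each pathway list with the smallest p in the comparisons that involve the treatment effect, and a set of fixed genes. Among the fixed genes, ESR1 and CYP1A4 (symbol LOC107318671) were matched. The names VTG1, VTG2, VTG3, APOV1, CYP7A1, CYP3A4 and SULT1E1 matched no symbol or synonym in the gene table, so vitellogenins and very-low-density apolipoprotein II are not analysed here under their own names. The name CYP7B1 was matched through a synonym, as was the egg-coat protein ZPD (LOC107319112). Named locus symbols are partly left out of the text. Marker genes and members of small counts of called list genes, where the rule does not name them, were chosen after their values were seen. Some genes that the rule names, or that belong to a list, are not reported here by name.

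For a single mixing share, each EE2 male was set in turn against mixtures of the solvent and other EE2 male means, over the genes called in males without it, on log2 (CPM + 0.1) with the spread pooled over the groups.

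The median log2 CPM of Z genes minus that of the other tested genes, with mitochondrial genes left out, was computed per library and compared between the sexes with a two-sided exact permutation test within each treatment (252 and 210 splits) and with 100000 permutations over all 20 libraries.

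The testing procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed by a known log2 fold change of 0.5, 1 or 2 in either direction. In the male comparison, 22.8%, 70% and 86.7% of the genes changed by 0.5, 1 and 2 were recovered among 13388 genes tested, and in the female comparison 38%, 63.3% and 88.1% among 13407. For the average effect the shares were 53.8%, 76.3% and 98.3% of 13395, and for the interaction 6.33%, 49.2% and 76.3% of 13368. For the sex difference they were 35%, 76.7% and 93.3% in solvent among 13389 and 42.5%, 72.9% and 93.2% in ethinylestradiol among 13381. False calls made up between 2.47% and 5.51% of the calls.

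Alternatives were the median-ratio size factors and the Wald test of DESeq2 1.42.0, limma voom, no filter on low counts, a stricter filter (log2 CPM of at least 1 in at least 4 libraries), the other deposited table, the replicate number of the titles as a block, 1 surrogate factor from sva 3.50.0, a fit of only the groups compared, additive and treatment-only models for the average effect, and leaving out each of the 20 libraries in turn. Upper-quartile scaling and subsets of the ethinylestradiol females were added after seeing the data.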

Results

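The liver transcriptome of male and female Japanese quail embryos was measured at embryonic day 9, after a single injection of the eggs with solvent (dimethyl sulfoxide, DMSO) or with ethinylestradiol (EE2), a synthetic estrogen, at 3.33 µg per g of egg. The study asks which liver responses to estrogen depend on sex. The groups held 5 solvent males, 5 solvent females, 4 EE2 males and 6 EE2 females. Total estimated counts lay between 15298506 in solvent female replicate 9 and 32119466 in solvent male replicate 2, and the other 18 libraries lay between 26776988 and 31847348. Between 14164 and 14812 genes had at least 1 count in a library, and log2 CPM of libraries of the same group correlated across genes with r between 0.956 and 0.978.

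Treatment separated the libraries. The first principal component of log2 CPM held 29.4% of the variance and lay between -41.62 and -26.4 in the 10 solvent libraries and between 22.45 and 44.12 in 9 of the 10 EE2 libraries. EE2 male replicate 3 lay between the groups at -1.45. On the second component, with 7.97% of the variance, EE2 males had a mean of 25.3 ± 13.4 (SD, n = 4) and EE2 females of -14.9 ± 12.3 (SD, n = 6). Mitochondrial transcripts took 5.86 ± 0.635% of the counts in EE2 females (SD, n = 6), against 7.16 ± 1.17% in solvent females (n = 5), 7.17 ± 0.345% in EE2 males (n = 4) and 7.15 ± 1.01% in solvent males (n = 5). The 10 most abundant genes took 22.5 ± 1.54% of the counts in EE2 females and 27.3 ± 2.12% in solvent females, and 27.5 ± 1.01% in EE2 males and 23.3 ± 2.11% in solvent males.

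**Figure D1:**
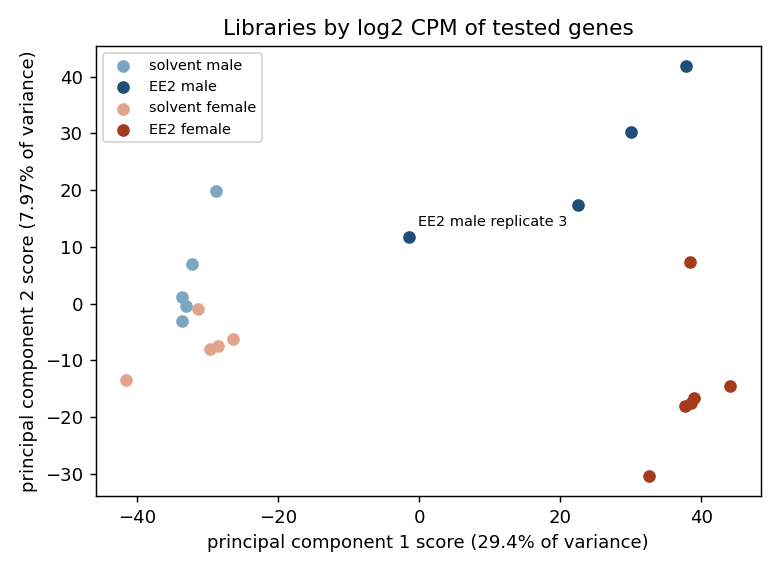
Principal components of log2 CPM over the tested genes, with the percent of variance of each component on its axis and 1 point per library, by sex and treatment. Solvent libraries lie between -41.62 and -26.4 on the first component, and the EE2 libraries between 22.45 and 44.12 except EE2 male replicate 3 at -1.45.

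In male embryos, EE2 raised a small set of transcripts from near the detection floor to high levels. LOC107319873, a locus without a gene name, went from 0.279 ± 0.139 CPM in solvent males (SD, n = 5) to 17560 ± 9060 CPM in EE2 males (SD, n = 4), a log2 fold change of 15.96 (SE 0.768, adjusted p = 1.79e-10). LOC107317565 went from 1.81 ± 0.459 to 29480 ± 13500 CPM, and LOC107317352 from 0.585 ± 0.353 to 6986 ± 2390 CPM. The egg-coat glycoprotein genes rose as well: ZP1 (gene 107314173), which bird liver makes under estrogen, went from 6.5 ± 5.66 to 183 ± 53 CPM, and ZPD (LOC107319112) from 0.0505 ± 0.0711 to 489 ± 317 CPM. APOB (gene 107312270), the apolipoprotein of yolk-bound lipoprotein particles, rose from 10620 ± 2100 to 38500 ± 1600 CPM, a log2 fold change of 1.86 (SE 0.16, adjusted p = 2.69e-07).

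In all, 302 genes rose and 139 fell in EE2 males among 13501 tested, and 156 of the former and 42 of the latter changed by at least 2-fold. Each of the 10 largest rises among named genes stood above the level of every solvent male in 4 of 4 EE2 males. They included ELOVL2 (gene 107309660), an elongase of polyunsaturated fatty acids, at 0.0343 ± 0.0422 CPM in solvent males and 20.9 ± 15.8 in EE2 males, and NPTXR at 0.289 ± 0.0981 and 131 ± 74.1 CPM. LOC107310248 had 1 count over the 5 solvent males and 78.2 ± 44.2 CPM in EE2 males, a ratio of 11700 with a 95% counting interval of 2090 to 460000. Among the genes that fell, the apolipoprotein gene APOA5 went from 388 ± 172 to 72.7 ± 23.1 CPM (log2 fold change -2.42, SE 0.349, adjusted p = 0.000314) and the transcription factor gene MYCL from 11.1 ± 3.09 to 2.63 ± 0.584 CPM. FABP2, an intracellular fatty acid carrier, fell by 4.21 on the log2 scale, from 33.1 ± 28.7 to 1.79 ± 0.701 CPM. Its call was lost without EE2 male replicate 4, 5 or 6, with log2 fold changes between -4.51 and -3.58 over the 20 fits that each left out a library. With limma voom, the male calls of ELOVL2 (8.65), LOC107310248 (11.62) and FABP2 (-3.57) were lost.

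Of 12 listed egg yolk precursor genes 5 were tested, and these include no vitellogenin and not APOV1, whose names matched no gene. In every comparison, tests of this list cover only these 5. Of the 5 tested egg yolk precursor genes, 3 rose in males (APOB, ZP1 and the retinol carrier RBP4, log2 fold change 0.73, SE 0.147) and 2 did not pass, TF at -0.50 (SE 0.249) and MTTP at -0.46 (SE 0.158). Adjusted over the list alone, 3 were higher and 1 lower. The list rose against other genes (camera adjusted p = 0.00185, and adjusted p = 0.0459 with an estimated correlation). Fatty acid and triglyceride synthesis had 5 of 17 members higher and 0 lower, or 6 and 1 adjusted over the list alone. AGPAT2, which makes phosphatidic acid, rose by 1.82 (SE 0.196) and ELOVL5 by 1.11 (SE 0.205). This list passed with an adjusted p = 0.000638, and with an adjusted p = 0.0459 with an estimated correlation. Fatty acid oxidation had 4 of 16 members lower and 0 higher, and 6 lower adjusted over the list alone. CPT1A, which admits fatty acids to mitochondria, fell by 0.96 on the log2 scale (SE 0.184). Its call was lost when only the male groups were fitted (-0.95). The oxidation list gave an adjusted p = 8.66e-07, and an adjusted p = 0.253 with an estimated correlation. In EE2 male replicate 3, which stood apart on the first component, LOC107319873 reached 4560 CPM and HSPA5 686 CPM, below the other 3 EE2 males.

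All 3 fibrinogen genes fell in males, FGA by 0.91 (SE 0.177), FGB by 0.88 (SE 0.18) and FGG by 0.89 (SE 0.184) on the log2 scale. When only the male groups were fitted, all 3 lost their call, at -0.90, -0.87 and -0.88. The other 17 of 20 coagulation and acute phase genes did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0526, and adjusted p = 0.706 with an estimated correlation). Of 18 endoplasmic reticulum folding genes 1 rose over all genes tested, CRELD2, and 11 rose adjusted over the list alone. The folding list gave an adjusted p = 4.86e-06, and an adjusted p = 0.308 with an estimated correlation. The call of CRELD2 was lost without solvent male replicate 2, 4 or 7 or EE2 male replicate 4, 5 or 6, with values of 0.67 to 0.91 over the 20 fits. The cell cycle list had 0 of 24 members called by edgeR and 0 by limma voom, 10 at an unadjusted p under 0.05, and 5 lower adjusted over the list alone. Its median log2 fold change was -0.28, with an adjusted p = 1.02e-07, and an adjusted p = 0.345 with an estimated correlation. Glucose metabolism had 2 of 15 members lower (6 adjusted over the list alone) with an adjusted p = 0.000638, and an adjusted p = 0.253 with an estimated correlation. Both members, G6PC (-0.76) among them, lost their calls when only the male groups were fitted. The other member also lost its call with DESeq2 size factors, upper-quartile scaling, the stricter filter, the surrogate factor and limma voom. Cholesterol synthesis had 2 of 21 higher (3 adjusted over the list alone), SQLE and EBP, with an adjusted p = 0.00327, and an adjusted p = 0.655 with an estimated correlation. SQLE kept its call only in the 4 fits without solvent male replicate 4, EE2 male replicate 3 or EE2 female replicate 7 or 8, with values of 0.83 to 1.76 over all 20. EBP lost its call without solvent male replicate 1, 2, 4 or 8 or EE2 male replicate 4, 5 or 6 (0.47 to 0.67). Xenobiotic metabolism had 2 of 8 lower (3 adjusted over the list alone), the aryl hydrocarbon receptor AHR and the heme synthesis enzyme ALAS1, with an adjusted p = 0.00696, and an adjusted p = 0.261 with an estimated correlation. AHR lost its call without solvent male replicate 1, 4, 7 or 8 or EE2 male replicate 4, 5 or 6 (-0.71 to -0.53). CRELD2 (0.78), SQLE (1.499), EBP (0.61) and AHR (-0.59) also lost their calls when only the male groups were fitted, SQLE (1.25) and EBP (0.56) with the surrogate factor, and SQLE with limma voom (1.35) and without the filter on low counts (1.48).

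The other pathway lists did not pass in males. Among their called members, the coactivator NCOA1 rose by 0.77 (SE 0.0744, adjusted p = 1.87e-06), catalase (CAT) by 0.66 (SE 0.129), and DIO2, which activates thyroid hormone, by 2.99 (SE 0.55) from 0.149 ± 0.0829 to 1.21 ± 0.271 CPM. Oxidative stress defence had 3 of 17 higher (3 adjusted over the list alone, adjusted p = 0.0611), and the macrophage markers, of which 0 of 9 were called by edgeR or limma voom and 0 had an unadjusted p under 0.05, also gave an adjusted p = 0.0611. Of the hepatocyte markers, APOB rose and FGB and APOA1 fell while 5 of 8 did not pass (adjusted p = 0.575). The call of APOA1 was lost without any 1 of the 5 solvent males or EE2 male replicate 4, 5 or 6, with values of -1.22 to -0.79 over the 20 fits. The endothelial, erythroid, mesenchymal, cholangiocyte, and granulocyte and lymphoid lists had 0 called members by edgeR and by limma voom, with 1, 0, 1, 0 and 0 at an unadjusted p under 0.05. The muscle list had 1 of 5 members called higher by edgeR and 0 by limma voom, with 2 higher adjusted over the list alone, and did not pass (adjusted p = 0.594). Its called member TNNT2 was higher in EE2 males (log2 fold change 3.48, adjusted p = 0.0395), where EE2 male replicates 5 and 4 held 58.5 and 14.8 CPM and the other 2 held 1.77 and 0.58. Its call was lost without any 1 of the 5 solvent males, solvent female replicate 5 or 6, or EE2 male replicate 4 or 5, with values of 1.76 to 3.88 over the 20 fits. Of 49 called gene results named for males under the rule, 30 kept their call whichever of the 20 libraries was left out, and 44 had 4 of 4 EE2 males beyond the range of all 5 solvent males. The count of 441 called genes fell to 254 without EE2 male replicate 4 and to 234 without EE2 male replicate 5, and was 647 without EE2 male replicate 3. It was 195 when only the male groups were fitted and 768 with the Wald test of DESeq2.

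In female embryos, EE2 changed more genes, 1375 higher and 1362 lower, of which 403 and 282 changed by at least 2-fold. The same loci led: LOC107319873 went from 11.3 ± 6.72 CPM in solvent females (SD, n = 5) to 19200 ± 3540 CPM in EE2 females (SD, n = 6), a log2 fold change of 10.74 (SE 0.62, adjusted p = 2.47e-09), and LOC107317565 from 11.4 ± 8.2 to 31070 ± 5110 CPM. ZP1 rose from 89.9 ± 26.6 to 267 ± 75.5 CPM (log2 fold change 1.57, SE 0.402) and APOB from 13030 ± 2960 to 36190 ± 2340 CPM (1.47, SE 0.148). NPTXR rose from 0.226 ± 0.223 to 163 ± 62.3 CPM, and CORIN, a protease that activates natriuretic peptide, from 0.0447 ± 0.0306 to 15.5 ± 2.02 CPM. Among the genes that fell, TNNC1, a troponin, went from 23 ± 11.5 to 2.61 ± 1.21 CPM (log2 fold change -3.14, SE 0.354, adjusted p = 6.45e-06), SRL from 26.4 ± 16 to 2.85 ± 2.13 CPM and the iodide transporter SLC5A5 from 5.19 ± 2.6 to 0.661 ± 0.43 CPM. LOC107307440 also passed in females, but fell by 3.20 with all libraries and by 0.22 on the log2 scale without solvent female replicate 6, which held 73 CPM. It also lost its call with limma voom (-1.48) and when only the female groups were fitted (-3.20).

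**Figure D2:**
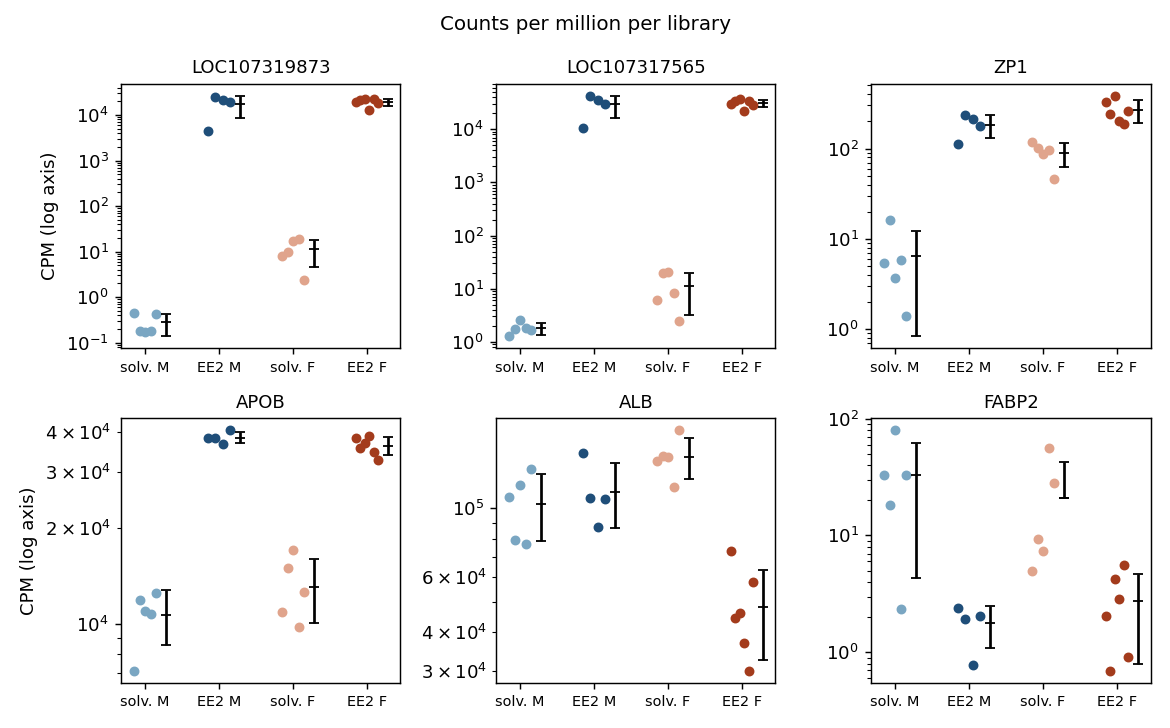
Level of 6 genes in CPM (log axis) in each library, by sex and treatment, with points for libraries and bars for the mean ± SD (upward only where the SD exceeds the mean, as for FABP2 in solvent females). LOC107319873 reached means of 17560 CPM in EE2 males and 19200 CPM in EE2 females, while ALB had a mean of 113300 CPM in EE2 males and 48090 CPM in EE2 females.

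Plasma protein genes of the hepatocyte fell in EE2 females. Albumin (ALB, gene 107313382) went from 146400 ± 21700 to 48090 ± 15500 CPM, a log2 fold change of -1.61 (SE 0.212, adjusted p = 2.86e-05), and transferrin (TF) from 49820 ± 13000 to 18200 ± 5930 CPM. Of the 8 tested hepatocyte markers 6 fell and 1, APOB, rose, with the same counts adjusted over the list alone (adjusted p = 1.47e-05, and adjusted p = 0.147 with an estimated correlation). Of 20 coagulation, complement and acute phase genes 12 fell and 2 rose, or 13 and 2 adjusted over the list alone. They included FGA, from 6732 ± 473 to 2658 ± 510 CPM, antithrombin (SERPINC1), which fell by 1.25 on the log2 scale (SE 0.152), and AMBP, which fell by 1.13 (SE 0.122). The coagulation list gave an adjusted p = 9.8e-08, and an adjusted p = 0.147 with an estimated correlation. It shares FGB, AMBP, AHSG and SERPINC1 with the hepatocyte list, so the lists are not independent here or in other comparisons. Beside these falls, the share of the 10 most abundant genes in EE2 females was 22.5% against 27.3% in solvent females. Among other cell types, the lists had medians of 1.09 (cholangiocyte), 0.33 (mesenchymal), 0.18 (macrophage), -0.09 (endothelial) and -0.44 (erythroid) in females, and none of these 5 passed (adjusted p between 0.0806 and 0.695). SPP1 and SOX9 rose and EPCAM fell among cholangiocyte markers, and DCN rose and RELN fell among mesenchymal markers. The call of DCN (0.49) was lost without solvent female replicate 10 (0.40). The macrophage, endothelial and erythroid lists had 0 members called by edgeR and by limma voom, with 0, 1 and 1 at an unadjusted p under 0.05. The granulocyte and lymphoid list had 0 of 4 called by either tool and 0 at an unadjusted p under 0.05 (adjusted p = 0.963), the muscle list 0 of 5 and likewise 0 (adjusted p = 0.654), and the kidney list 1 of 3, CUBN, higher (adjusted p = 0.854). The kidney list had a median of -0.26 and a mean of 0.84, and its test pointed up, while the granulocyte and lymphoid list had a median of -0.04 and a mean of 0.03, and its test pointed down.

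Fatty acid oxidation genes fell in females, with 14 of 16 members lower and 0 higher over all genes tested, and 14 lower and 1 higher adjusted over the list alone (adjusted p = 3.99e-10, and adjusted p = 0.147 with an estimated correlation). ACSL1, which activates long-chain fatty acids, went from 356 ± 30.3 to 161 ± 33.1 CPM, and ETFDH from 216 ± 44.7 to 113 ± 9.59 CPM. Fatty acid and triglyceride synthesis had 7 of 17 members higher and 0 lower, or 8 and 3 adjusted over the list alone. Fatty acid synthase (FASN) rose from 43.5 ± 5.41 to 103 ± 19.7 CPM, LPIN1 from 1.15 ± 0.0835 to 9.96 ± 3.07 CPM and AGPAT2 from 22.2 ± 3.58 to 120 ± 7.58 CPM, with 6 of 6 EE2 females above every solvent female for each. The synthesis list gave an adjusted p = 0.00136, and an adjusted p = 0.115 with an estimated correlation. Of 21 cholesterol genes 12 rose and 2 fell, or 13 and 2 adjusted over the list alone (adjusted p = 0.000162, and adjusted p = 0.362 with an estimated correlation). Squalene epoxidase (SQLE) rose by 2.26 (SE 0.39) and HMGCS1 by 1.46 (SE 0.223).

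Folding and stress genes of the endoplasmic reticulum rose in females, 9 of 18 over all genes tested and 12 adjusted over the list alone, with 0 lower (adjusted p = 1.42e-05, and adjusted p = 0.264 with an estimated correlation). The chaperone HSPA5 went from 718 ± 71.5 to 1489 ± 442 CPM, CRELD2 rose by 1.32 (SE 0.174) and the stress-induced transcription factor ATF3 by 2.81 (SE 0.404). Glucose metabolism had 8 of 15 lower and 1 higher, or 9 and 3 adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.21 with an estimated correlation). Glucose-6-phosphatase (G6PC) fell by 1.02 on the log2 scale (SE 0.154) and glycogen phosphorylase (PYGL) fell by 0.60 (SE 0.0848). Of 12 bile acid genes 7 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.00844, and adjusted p = 0.147 with an estimated correlation). KLB, the coreceptor for FGF19, went from 174 ± 13.1 to 82.1 ± 17.7 CPM, the bile acid receptor NR1H4 fell by 0.74 (SE 0.136), and the efflux transporter subunit SLC51B rose from 12 ± 8.97 to 44.5 ± 11.5 CPM. Extracellular matrix had 5 of 25 higher and 0 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.00473, and adjusted p = 0.507 with an estimated correlation). Xenobiotic metabolism had 3 of 8 lower, or 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0217, and adjusted p = 0.264 with an estimated correlation), and CYP1A4 went from 416 ± 128 to 177 ± 55.7 CPM. The cell cycle list had 0 of 24 called by edgeR and by limma voom and 3 at an unadjusted p under 0.05, with a median of -0.19 and an adjusted p = 0.0109, and an adjusted p = 0.725 with an estimated correlation.

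**Figure D3:**
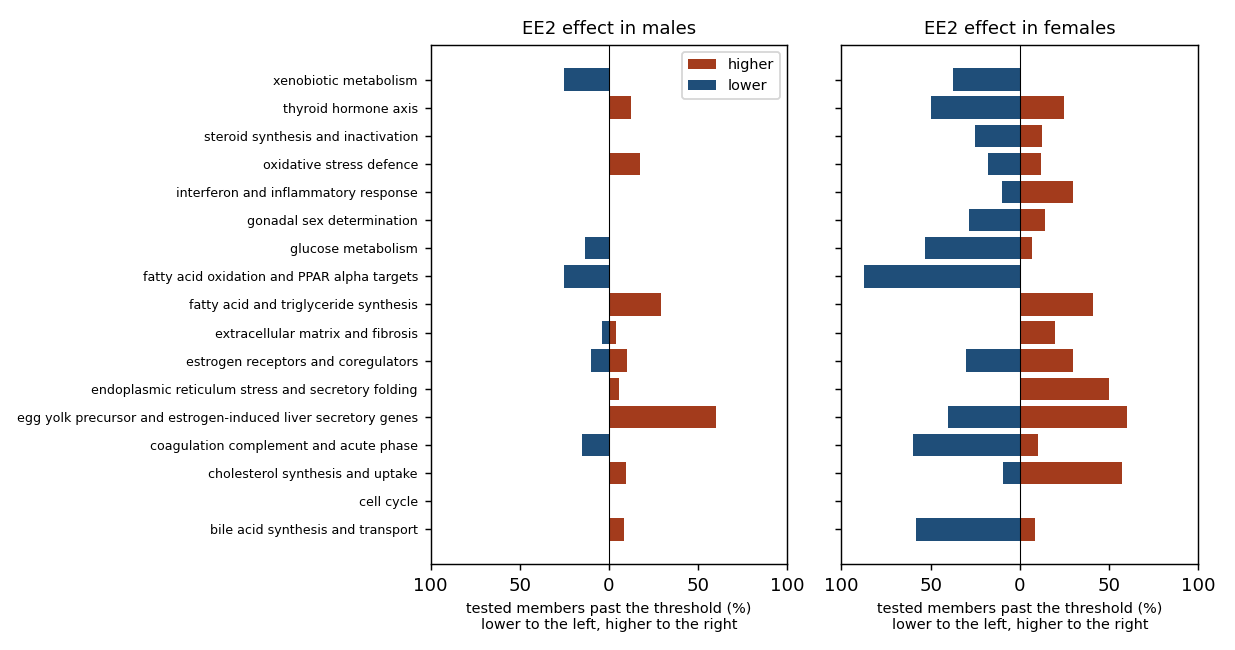
Percent of the tested members of each fixed pathway list called higher or lower with EE2 in males and in females, as bars on either side of 0. Fatty acid oxidation had 14 of 16 members lower in females and 4 of 16 lower in males.

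The remaining lists did not pass in females. Of the 5 tested egg yolk precursor genes, APOB, ZP1 and RBP4 rose and TF and the lipid transfer protein MTTP fell (3 and 2 adjusted over the list alone, adjusted p = 0.616). The vitellogenins and APOV1 were not tested under their names, so this result says nothing of them. The call of RBP4 was lost without solvent female replicate 3, 5, 9 or 10 or EE2 female replicate 2, 7, 8 or 10 (0.33 to 0.48). Of 10 estrogen receptor and coregulator genes, 3 rose, NCOA1 and GREB1 among them, and PGR, NCOA2 and ESRRG fell (3 and 4 adjusted over the list alone, adjusted p = 0.956). The median of this list was -0.01, its mean was 0.24 and its test pointed up. PGR lost its call without solvent female replicate 3, 5 or 9 or EE2 female replicate 1, 7, 8 or 9 (-1.08 to -0.66). ESRRG went from 27.2 ± 3.21 to 14.6 ± 1.59 CPM. In the thyroid list, 4 of 8 fell, among them ALB, and 2 rose (4 and 2 adjusted over the list alone, adjusted p = 0.0544). In oxidative stress defence 2 of 17 rose and 3 fell (2 and 7 adjusted over the list alone, adjusted p = 0.205), with TXNRD1 higher by 2.48 (SE 0.311) and SOD1 lower at -0.89 (SE 0.123). Steroid synthesis had 1 of 8 higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.662). Gonadal sex determination had 1 of 7 higher, SOX9, and 2 lower, RSPO1 and UBAP2, with the same counts adjusted over the list alone (adjusted p = 0.616). RSPO1 lost its call without solvent female replicate 3, 5 or 9 or EE2 female replicate 7, 8 or 9 (-0.96 to -0.64), and UBAP2 without solvent female replicate 3, 5 or 10 or EE2 female replicate 2 or 9 (-0.19 to -0.13). UBAP2 also lost its call when only the female groups were fitted (-0.16) and with upper-quartile scaling (-0.13).

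The interferon and inflammatory list had 3 of 10 members higher in females, NFKBIA, SOCS3 and TNFAIP3, and 1 lower, IFIH1 (3 and 2 adjusted over the list alone, adjusted p = 0.812). Its median was -0.39 and its mean 0.04, and its test pointed up. IFIH1 lost its call without solvent female replicate 3, 9 or 10 or EE2 female replicate 7, 8, 9 or 10 (-0.93 to -0.70). It also lost its call with the surrogate factor (-0.61). The mean log2 CPM of this list lay between 2.49 and 3.29 in 16 libraries and at 4.84, 4.06, 3.60 and 4.61 in solvent male replicates 2 and 7, solvent female replicate 9 and EE2 male replicate 3. Of 82 called gene results named for females, 74 kept their call whichever library was left out, and 71 had 6 of 6 EE2 females beyond the range of all 5 solvent females.

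Averaged over the sexes with equal weight, the EE2 effect was called for 1388 genes higher and 1390 lower. LOC107319873 had a log2 fold change of 13.35 (SE 0.493), AGPAT2 of 2.12 (SE 0.136) and NCOA1 of 0.81 (SE 0.0505). The folding list had 13 of 18 members higher and 0 lower (13 adjusted over the list alone, adjusted p = 5.96e-07, and adjusted p = 0.214 with an estimated correlation), and fatty acid oxidation 13 of 16 lower (14 adjusted over the list alone, adjusted p = 1.73e-10, and adjusted p = 0.148 with an estimated correlation). Fatty acid and triglyceride synthesis had 8 of 17 higher and 1 lower, or 10 and 1 adjusted over the list alone, with an adjusted p = 0.00014, and an adjusted p = 0.0441 with an estimated correlation. Hepatocyte markers had 1 of 8 higher and 6 lower, with the same counts adjusted over the list alone (adjusted p = 0.000543, and adjusted p = 0.214 with an estimated correlation). Coagulation had 2 of 20 higher and 10 lower, or 2 and 13 adjusted over the list alone (adjusted p = 9.08e-06, and adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis had 11 of 21 higher and 1 lower, or 14 and 1 adjusted over the list alone (adjusted p = 5.55e-05, and adjusted p = 0.301 with an estimated correlation). Glucose metabolism had 1 of 15 higher and 9 lower, with the same counts adjusted over the list alone (adjusted p = 0.00014, and adjusted p = 0.214 with an estimated correlation), and xenobiotic metabolism 3 of 8 lower, or 4 adjusted over the list alone (adjusted p = 0.00305, and adjusted p = 0.214 with an estimated correlation). Of 24 cell cycle genes 7 fell and 0 rose, or 14 lower adjusted over the list alone (adjusted p = 7.84e-06, and adjusted p = 0.374 with an estimated correlation). Their falls were small, MKI67 at -0.34 (SE 0.103) and CDK1 at -0.34 (SE 0.104). Both calls, as that of E2F1, were lost without EE2 male replicate 4 or 5, with values over the 20 fits of -0.42 to -0.30 for MKI67, -0.41 to -0.30 for CDK1 and -0.28 to -0.20 for E2F1. MKI67 also lost its call with the surrogate factor (-0.29). Of the fixed genes, CYP1A4 fell by 0.79 (SE 0.164, adjusted p = 0.00196). The estrogen receptor gene ESR1 (gene 107311566) had a log2 fold change of 0.02 (SE 0.165, adjusted p = 0.951), from 0.57 (SE 0.246, adjusted p = 0.237) in males and -0.54 (SE 0.219, adjusted p = 0.0922) in females, and the difference between these effects did not pass (-1.11, SE 0.33, adjusted p = 0.111).

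The responses of the sexes overlapped. Of the genes called in both, 217 were higher in both and 94 lower in both, against 30.8 and 14 for independent lists of these sizes, and 0 had opposite signs. The comparisons share no control library, but both used the same spread per gene, estimated over all groups. Genes with a small spread are called more easily in both sexes, so the numbers for independent lists are not an exact reference. Another 130 genes were called in males alone and 2426 in females alone, 93.42% of the male calls had the same sign in females, and 82.13% of the female calls had the same sign in males. Across all tested genes, which are not independent replicates, log2 fold changes correlated with r = 0.626. The median ratio of female to male log2 fold change among genes called in both was 1.01.

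**Figure D4:**
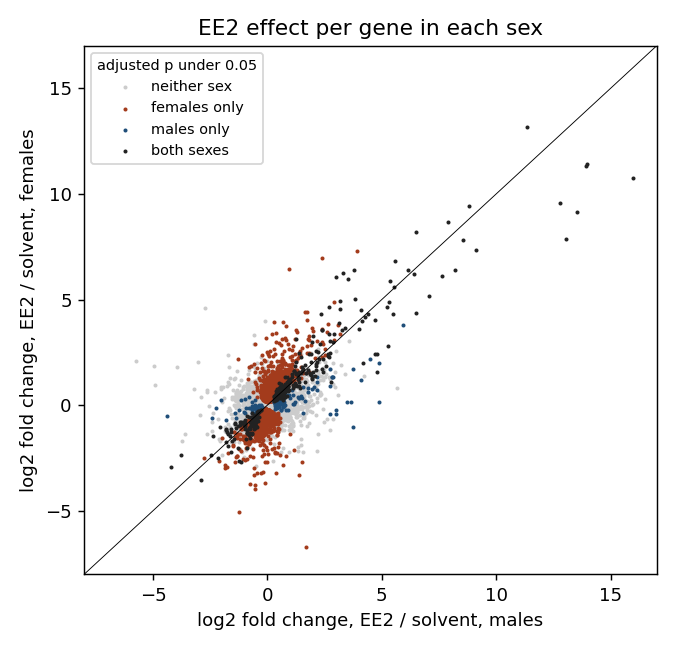
Log2 fold change with EE2 in males (horizontal axis) and in females (vertical axis), 1 point per tested gene. Colours mark genes called in neither sex, in females only, in males only or in both sexes, not the test of the difference. Of the genes called in both sexes, 217 were higher in both, 94 lower in both and 0 had opposite signs.

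The difference between the female and male effects itself passed for 143 genes, 35 with the more positive change in females and 108 with the more negative. LOC107319873 had an interaction of -5.22 (SE 0.73, adjusted p = 0.0122), with 0.279 CPM in solvent males and 11.3 CPM in solvent females against 17560 and 19200 CPM after EE2. ZP1 had an interaction of -3.23 (SE 0.59, adjusted p = 0.0232), with 6.5 and 89.9 CPM in solvent males and females against 183 and 267 CPM after EE2. ALB had log2 fold changes of 0.13 in males and -1.61 in females, an interaction of -1.74 (SE 0.313, adjusted p = 0.0232). The calcium channel gene RYR3 had values of 0.66 and -2.84 (interaction -3.50, SE 0.582), TNNC1 of -0.20 and -3.14 (-2.94, SE 0.499), and the secretogranin SCG2 of 3.75 and -1.02 (-4.78, SE 0.752). In the other direction, osteopontin (SPP1) had log2 fold changes of 0.03 in males and 2.40 in females (interaction 2.37, SE 0.438, adjusted p = 0.0232) and ALAS1 of -0.82 and 0.40 (1.22, SE 0.23).

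Of the 143 genes, 119 were called in females alone, 14 in males alone, 7 in both and 3 in neither. The sizes were larger in females for 118 and in males for 25, and the signs were opposite for 79. Of the 2426 genes called in females alone, 119 passed this test of the difference, and of the 130 called in males alone, 14 did. The hepatocyte list was lower in the interaction, with 2 of 8 members called, ALB and AMBP (5 adjusted over the list alone, adjusted p = 4e-07, and adjusted p = 0.0982 with an estimated correlation). Coagulation had 1 of 20 lower (6 adjusted over the list alone, adjusted p = 2.41e-06, and adjusted p = 0.194 with an estimated correlation). The egg yolk list had 1 of 5 lower, ZP1 (2 adjusted over the list alone, adjusted p = 0.000446, and adjusted p = 0.0302 with an estimated correlation). Vitellogenins and APOV1 were not among these 5. Oxidative stress defence had 2 of 17 lower, CAT and SOD1 (adjusted p = 0.00328, and adjusted p = 0.0982 with an estimated correlation), and fatty acid oxidation 1 of 16, ACAA2 (adjusted p = 0.00328, and adjusted p = 0.565 with an estimated correlation). Extracellular matrix had 1 of 25 higher, TGFB2 (adjusted p = 0.00871, and adjusted p = 0.62 with an estimated correlation), bile acids 1 of 12 lower, KLB (adjusted p = 0.00881, and adjusted p = 0.0982 with an estimated correlation), and the thyroid list 2 of 8 lower, ALB and DIO2 (adjusted p = 0.0316, and adjusted p = 0.0982 with an estimated correlation). Adjusted over the list alone, these last 5 lists had 2, 2, 1, 3 and 4 members in the direction of the list. AMBP lost its call without solvent male replicate 2 or 7, solvent female replicate 10, EE2 male replicate 3 or 4, or EE2 female replicate 7, 9 or 10 (-0.92 to -0.74 over the 20 fits). DIO2 lost its call without solvent male replicate 2 or 7, solvent female replicate 6, EE2 male replicate 3 or 4, or EE2 female replicate 10 (-3.74 to -2.97). ZP1 lost its call without EE2 male replicate 4 (-3.09). ACAA2 kept its call only without solvent male replicate 4 or 8, solvent female replicate 5, 9 or 10, EE2 male replicate 5, or EE2 female replicate 1, 2 or 8 (-0.58 to -0.46). CAT kept its call only without solvent male replicate 8, solvent female replicate 5 or 9, EE2 male replicate 5, or EE2 female replicate 1 or 2 (-0.85 to -0.66). KLB kept its call only without solvent male replicate 8, solvent female replicate 9, EE2 male replicate 5 or EE2 female replicate 1 (-1.03 to -0.77). SOD1 kept its call only without solvent female replicate 9, EE2 male replicate 5 or EE2 female replicate 10 (-0.87 to -0.68), and TGFB2 only without solvent male replicate 7, solvent female replicate 10 or EE2 male replicate 5 (1.21 to 1.64). SOD1 and TGFB2 also lost their calls with limma voom (-0.75 and 1.43), without the filter on low counts (-0.76 and 1.40) and with the surrogate factor (-0.78 and 1.39).

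The interaction count depended on single libraries. Left out in turn, solvent male replicates 1, 2, 4 and 7 gave 94, 81, 95 and 62 genes, solvent female replicates 3, 5, 6 and 10 gave 81, 87, 50 and 43, EE2 male replicates 3, 4 and 6 gave 24, 21 and 68, and EE2 female replicates 7, 8, 9 and 10 gave 70, 81, 53 and 66, while the other 5 libraries gave counts within 1.5 times of 143, up to 191 without solvent female replicate 9. Of 30 called gene results named for the interaction, 6 kept their call whichever library was left out: LOC107319873, LOC107317030, SCG2, RYR3, TNNC1 and ALB. With limma voom, 3 of these 6 lost their call, LOC107319873 (-4.71), LOC107317030 (3.28) and SCG2 (-4.63). The calls of ZP1, SPP1 and ALAS1 were lost without EE2 male replicate 4 alone, each with an adjusted p = 0.0508, at values within -3.90 to -2.98, 1.95 to 2.51 and 1.12 to 1.30 over the 20 fits. The DESeq2 Wald test called 454 genes and limma voom 102.

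Solvent embryos, which give the sex difference without exposure, differed between the sexes mainly on the Z chromosome, of which male birds carry a pair and females a single copy. Of 232 called genes, 190 were lower and 42 higher in females, and 178 of the 190 lay on Z. The median log2 fold change of the 601 tested Z genes was -0.41, against 0.00415 for the other genes. Z genes with the largest falls included TUSC1, at 29.2 ± 1.9 CPM in solvent males and 13 ± 1.9 in solvent females (SD, n = 5 each), SRFBP1 at 33 ± 1.06 and 15.1 ± 2.22 CPM, and PLIN2, a lipid droplet coat protein, at 353 ± 73.4 and 152 ± 28.7 CPM (log2 fold change -1.22, SE 0.162, adjusted p = 6.47e-05). ZP1 and LOC107319873, both called higher with EE2 in each sex, were higher in solvent females by 3.78 (SE 0.46, adjusted p = 3e-05) and 5.35 (SE 0.601). The estrogen receptor gene ESR1 was higher in solvent females by 1.26 (SE 0.235, adjusted p = 0.00314), at 12.5 ± 2.4 CPM in females and 5.23 ± 2.14 in males. The call of ESR1 was lost when only the solvent groups were fitted (1.26).

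GPR50 and SLC1A1 were also higher in solvent females, by 2.21 (SE 0.321) and 1.07 (SE 0.215). The egg yolk list had 1 of 5 members higher, ZP1 (1 adjusted over the list alone, adjusted p = 0.0387, and adjusted p = 0.183 with an estimated correlation). Gonadal sex determination had 2 of 7 lower, the Z genes HINT1 and UBAP2 (2 adjusted over the list alone, adjusted p = 0.0116, and adjusted p = 0.183 with an estimated correlation). Extracellular matrix was lower as a list, with 0 of 25 members called by edgeR and by limma voom, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The list gave an adjusted p = 0.00484, and an adjusted p = 0.631 with an estimated correlation. Per library, the median of Z genes minus that of other genes was -0.697 ± 0.0224 in solvent females (SD, n = 5) and -0.242 ± 0.0419 in solvent males (n = 5; exact permutation p = 0.00794, the smallest that 252 splits allow). In EE2 embryos it was -0.670 ± 0.0219 in females (n = 6) and -0.173 ± 0.0421 in males (n = 4; exact permutation p = 0.00476, the smallest that 210 splits allow). All 11 females lay at or below -0.644 and all 9 males at or above -0.278, so that each library stood with its labelled sex (difference -0.471, permutation p = 1e-05, the smallest that 100000 permutations can give). Leaving out single libraries left the solvent count between 202 and 234.

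**Figure D5:**
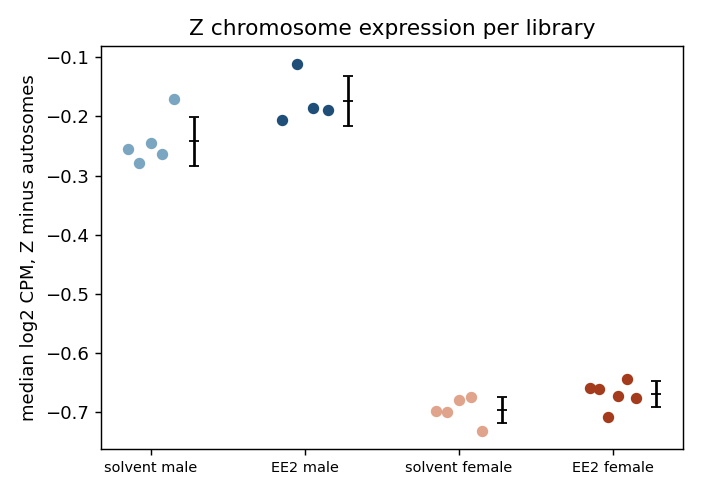
Median log2 CPM of Z genes minus the median of other tested genes, 1 point per library, by sex and treatment, with bars for the mean ± SD. The 11 females lie at or below -0.644 and the 9 males at or above -0.278.

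After EE2, the sexes differed in 873 genes, 299 higher and 574 lower in females, and 235 of the lower genes lay on Z. ALB was lower in EE2 females by 1.24 on the log2 scale (log2 fold change -1.24, adjusted p = 0.00157), at 48090 ± 15500 CPM (SD, n = 6) against 113300 ± 26700 CPM in EE2 males (SD, n = 4). SPP1 was higher in females at 64.3 ± 26.3 against 22 ± 3.53 CPM, the growth factor EREG at 7.43 ± 2.33 against 1.86 ± 0.435 CPM, and the phosphatase DUSP10 at 17.7 ± 9.27 against 5.13 ± 2.47 CPM. SCG2 was lower in females at 0.668 ± 0.551 against 16.4 ± 15.2 CPM (log2 fold change -4.60, SE 0.54, adjusted p = 1.65e-05). ZP1 at 0.55 (SE 0.418), APOB at -0.09 (SE 0.152) and RBP4 at -0.47 (SE 0.14) did not pass between the EE2 groups. The egg yolk list had 0 of 5 members called by edgeR and by limma voom, 3 at an unadjusted p under 0.05, and 0 higher and 3 lower adjusted over the list alone (adjusted p = 0.217).

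Hepatocyte markers had 4 of 8 lower and 0 higher in EE2 females, ALB, AMBP, AHSG and SERPINC1 (6 lower adjusted over the list alone, adjusted p = 1.81e-05, and adjusted p = 0.213 with an estimated correlation), and coagulation 6 of 20 lower (10 adjusted over the list alone, adjusted p = 1.76e-06, and adjusted p = 0.213 with an estimated correlation). Fatty acid oxidation had 4 of 16 lower, CPT2, HADHB, ACAA2 and ETFDH (8 adjusted over the list alone, adjusted p = 5.58e-05, and adjusted p = 0.255 with an estimated correlation), and oxidative stress defence 2 of 17, GSR and SOD1 (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.0433, and adjusted p = 0.213 with an estimated correlation). Without EE2 male replicate 3, AHSG (-1.36), ETFDH (-0.42), GSR (-0.48), HADHB (-0.40) and CPT2 (-0.28) did not pass. HADHB also lost its call without EE2 male replicate 4 or EE2 female replicate 9 or 10 (-0.55 to -0.40), and CPT2 without solvent male replicate 1, EE2 male replicate 4 or EE2 female replicate 1, 7, 8, 9 or 10 (-0.49 to -0.28).

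The muscle genes MYL2 at -4.61 (SE 0.934), TNNT2 at -4.20 (SE 0.872), ACTC1 at -3.71 (SE 1.01) and MYL3 at -3.31 (SE 0.923) were called lower in EE2 females by edgeR. None of the 4 was called by limma voom (adjusted p between 0.187 and 0.536). The fixed muscle list did not pass, with 2 of 5 members lower, TNNT2 and ACTC1, and 2 adjusted over the list alone (adjusted p = 0.425). EE2 male replicate 5 held 84.4 CPM of ACTC1 and EE2 male replicate 4 held 20 CPM. Without EE2 male replicate 5 these values were -2.73, -2.47, -2.02 and -1.29, and none of the 4 passed. ACTC1 and MYL3 also lost their calls without EE2 male replicate 4 or EE2 female replicate 2, 7, 8, 9 or 10 (-4.92 to -2.02 for ACTC1 and -3.71 to -1.29 for MYL3). When only the EE2 groups were fitted, ACTC1 (-3.72), MYL3 (-3.31) and TNNT2 (-4.20) lost their calls. The helicase DDX60 was lower at -5.14 (SE 1.49), with 435 CPM in EE2 male replicate 3, and without that library its value was -0.34. DDX60 also lost its call without solvent female replicate 3, 5, 6 or 10 or any 1 of the 6 EE2 females (-5.54 to -0.34). Its call was lost with limma voom (-2.01), without the filter on low counts (-5.13) and with the surrogate factor (-0.72) as well. Without EE2 male replicate 3 the count of called genes was 446, and with DESeq2's Wald test it was 1311.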

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

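The test of a single mixing share for all genes, settled after other forms of it had been tried, the tests of cell composition and of counts taken up by induced transcripts, and the subsets of EE2 females were chosen after the result was seen. The other tests on EE2 male replicate 3 are later additions too, since that library was picked by its place on the first principal component. Chance marks about 1 in 20 groups for a library far from the others: of 128 tests on library measures 13 were marked where 6.4 would be 1 in 20, and of 608 tests on named genes 49 were marked where 30.4 would be.

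EE2 male replicate 3 stood apart from the other 3 EE2 males in several measures. Its levels were 4560 CPM for LOC107319873, 343 for LOC107314278, 3480 for LOC107317352, 18.6 for ELOVL5, 111 for NR1H4, 686 for HSPA5 and 435 for DDX60, its mean log2 CPM was 6.97 for the folding list and 4.61 for the interferon list. A solvent embryo under an EE2 label is argued against, since the 20 genes most induced in females stood at a median of 30.5% of the mean of the other EE2 males, against 0.293% in solvent males. Mixing with solvent RNA stays open. The 20 genes most induced in females showed a median share of the male response of 0.305. The 100 genes with the smallest p among those lower in females showed 0.226 (interquartile range -0.192 to 0.502), a difference of 0.0789. These lowered genes were chosen in females and need not respond in males, so their shares are unstable. The closeness of the 2 medians therefore does not decide about mixing. At the best single share of 0.41, 2.02% of 645 responding genes lay beyond their 99% limits, against 1.61% to 1.99% in the other EE2 males. Single genes picked by their values went against a low share, such as APOB at 38467 CPM, inside the 36645 to 40558 CPM of the other EE2 males, and a weaker response of this embryo, which was not tested, may give such values as well.

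More genes were called for EE2 in females than in males, 2737 against 441. The number of libraries is argued against as the whole cause, since the 15 subsets of 4 EE2 females gave at least 1906 genes, with a median of 2165. The library of EE2 male replicate 3 is argued against as well, since without it the male count was 647, below the lowest of 20 subsets of 3 EE2 females, 1435. Sex of the embryo and a larger spread among the EE2 males stay open, and neither is shown to be the cause.

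Hepatocyte plasma protein genes were lower in EE2 females, 6 called members falling by 1.13 to 1.62 on the log2 scale. A lower share of hepatocytes would raise the lists of other cell types alike, but 4 pairs of the 5 lists had interquartile ranges that lay apart, each involving the erythroid list, whose median was -0.44 where that of the mesenchymal list was 0.33. Counts taken up by the 44 strongly induced transcripts, 7.02% of the total, could lower all other genes by -0.105 at most. A lower hepatocyte share together with a separate change in red cells stays open: markers put the hepatocyte share of the counts in solvent females at 21.1% or more, so that other genes would need to rise by at least 0.181 on the log2 scale of CPM without TMM scaling, where the endothelial list, the lowest of the other 4, had a median of 0.198 with quartiles of 0.132 and 0.391. The full share of hepatocyte RNA is not known from these data, and a response of the hepatocytes themselves also stays open and was not tested.

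Other splits of the same libraries into groups of the same sizes were drawn 100 times for each comparison, the real split included. In each of the 6 comparisons only 1 split, the real one, gave as many genes, the smallest share that 100 draws allow. For the EE2 effects and the sex differences this argues against a random split as the source of the whole count, not of single genes. The real differences stayed in the redrawn groups and widened their spread, so their counts do not estimate false calls. For the interaction these splits cannot exclude chance, since redrawing the sex labels also broke up the sex difference on Z. The real counts and the highest of the other splits were 441 and 49 in males, 2737 and 1420 in females, 2778 and 43 for the average, 143 and 1 for the interaction, 232 and 2 for sex in solvent and 873 and 12 for sex in EE2. The split with 1420 genes drew 1 true EE2 library among its 6, so that it nearly inverted the real groups.

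Among library measures, solvent female replicate 9 had the lowest total estimated count in its group, 15298506, and EE2 male replicate 5 had 26776988 in its group. Mean log2 CPM of a list lay far from the group in EE2 female replicate 9 for cholangiocyte markers (4.57), solvent female replicate 10 for hepatocyte markers (13.25), EE2 female replicate 10 for bile acids (5.18), solvent male replicate 8 for fatty acid oxidation (8.18) and solvent female replicate 5 for xenobiotic metabolism (6.25). Interferon genes averaged 3.60 in solvent female replicate 9. Muscle markers averaged -0.46 in solvent male replicate 4 and 1.78 in EE2 female replicate 1, whose mesenchymal markers averaged 6.88.

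Single genes with a library far from its group are given in CPM. Over the 5 solvent males, LOC107310248 had 1 count, with 4 libraries at 0, and MYL2 had 30. Their marks in solvent males therefore rest on few counts. Solvent males had 0.0343 for LOC107310248, 0.103 for MYL2, 0.343 for ACTC1 and 0.687 for TTN in replicate 4, 7090 for APOB and 516 for LOC107318671 in replicate 1, 249 for PYGL, 10.1 for SOX9 and 53.9 for HSD17B12 in replicate 2, and 4.37 for LOC116653849 and 50.5 for METTL27 in replicate 7. Solvent females had 0.521 for LOC107317574 and 73 for LOC107307440 in replicate 6, 29.7 for LOC107312420, 94.9 for ABCG2 and 1.7 for LEF1 in replicate 5, and 68.1 for NCOA1, 0.98 for LOC107317030 and 5.58 for CEP126 in replicate 3. They also had 25.4 for GCLC, 963 for HSP90B1 and 21.4 for DDX60 in replicate 9, and 2950 for AMBP, 295 for ETFDH and 771 for ACAA2 in replicate 10. EE2 males had 3.51 for MYCL and 0.783 for SLC5A5 in replicate 4, 8.57 for TGFB2 in replicate 5, and 1.5 for TNFAIP3, 9.52 for PDE2A and 13.2 for DNAAF3 in replicate 6. EE2 females had 12700 for LOC107319873, 2800 for LOC107317352, 4.97 for ELOVL2 and 335 for CPT1A in replicate 8, 7.15 for LOC107312420 and 3.26 for DNAAF3 in replicate 7, 0.23 for LOC107308972, 2.63 for CEP126 and 3.39 for TNNT2 in replicate 1, and 4.03 for LOC107322603 in replicate 10.

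The test of the difference between the female and male EE2 effects passed for 30 named genes with all libraries. Of these 30, 6 kept their call whichever library was left out, and all 30 lost it with the replicate block. Few replicate numbers joined embryos of the same sex, so the loss with the block does not decide against the interaction. Lost with limma voom were PCK1, LOC107317030, EREG, CACNA1H, LPIN1, CAPRIN2, LEF1, TGFB2, FASN, LOC107319873, LOC107319112, SCG2, LOC107317352, LOC107317565 and SOD1. PCK1, LOC107317565, TGFB2 and SOD1 also lost their calls without the filter on low counts. The female minus male log2 fold change was above 0 for PCK1 (5.07), LOC107317030 (3.46), EREG (2.64), SPP1 (2.37), GDF15 (2.25), CACNA1H (1.87), LPIN1 (1.86), CAPRIN2 (1.71), HMGCS1 (1.56), LEF1 (1.53), TGFB2 (1.39), ALAS1 (1.22) and FASN (0.91). It was below 0 for LOC107319873 (-5.22), LOC107319112 (-5.20), SCG2 (-4.78), LOC107317352 (-4.41), RYR3 (-3.50), DIO2 (-3.38), CEP126 (-3.29), ZP1 (-3.23), LOC107317629 (-2.98), TNNC1 (-2.94), LOC107317565 (-2.59), ALB (-1.74), KLB (-0.92), AMBP (-0.84), CAT and SOD1 (both -0.77) and ACAA2 (-0.55).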

How the results depend on the processing

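Upper-quartile scaling and the subsets of EE2 females were chosen after seeing the data. The counts for the average effect and for sex in solvent stayed within 1.5 times under every alternative run except the replicate block for the latter. No scaling moved the median of all genes by over 0.1 or the share of higher calls by over 10 points. The Wald test of DESeq2 called 768 genes in males, 454 for the interaction and 1311 for sex in EE2; the cause was not tested. A fit of the male groups alone called 195. The same kind of fit called 2632 in females, 177 for sex in solvent and 685 for sex in EE2, each within 1.5 times of the main count. Fewer libraries estimate the spread in all of these fits, and the cause of the larger drop in males was not tested. Of leave-one-out fits, males gave 234 to 647, females 2080 to 2855, the average 2086 to 3059, the interaction 21 to 191, sex in solvent 202 to 234, sex in EE2 446 to 956, the correlation of male and female effects 0.574 to 0.646, and the Z difference -0.479 to -0.458. That correlation was 0.768 for genes with a mean log2 CPM of at least 3 and 0.419 as Spearman's rho.

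With the replicate block, the calls numbered 52 in males, 877 in females, 0 for the interaction (by edgeR, with 1080 genes at an unadjusted p under 0.05 in the same fit; no other tool was run with the block), 47 for sex in solvent and 99 for sex in EE2. The labels do not say whether the replicate numbers pair the embryos, and the values gave little sign of it. Deviations from the group means of the 10 pairs correlated with r between -0.0185 and 0.136, 2 over 0.1, and 1 library correlated best with its own number. A weak effect shared within a number is not excluded by these values. Fewer residual degrees of freedom belong to this fit by construction. Only number 4 was male in both treatments, and only numbers 9 and 10 were female in both. The other numbers joined opposite sexes, so the effects within a sex and the interaction rested on few pairs of the same sex. The average effect kept 2176 calls. Lower counts with the block can follow from this layout, so they do not decide against the interaction. With the replicate block LOC107318671 turned sign in males (0.0133) and for sex in solvent (0.28), neither of them called.

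Signs also turned for values near 0 that were never called; the cause was not tested. LOC107318671 for sex in solvent was 0.0089 without solvent male replicate 1, 0.0441 without solvent female replicate 3 and 0.0133 without solvent female replicate 5, and lowest at -0.222 without solvent female replicate 10. The average effect on ESR1 was -0.10 with the surrogate factor, -0.0457 in the additive model, -0.0931 with treatment alone, and -0.0091, -0.0132, -0.0161, -0.0770, -0.052 and -0.0025 without solvent male replicate 2, solvent female replicates 3 and 5, solvent male replicate 7, EE2 male replicate 6 and EE2 female replicate 7, with a highest value of 0.128 without solvent male replicate 1.

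Lists past the threshold numbered 8 in males, 11 in females, 9 for the average, 8 for the interaction, 3 for sex in solvent and 4 for sex in EE2 with the preset correlation. With an estimated correlation they numbered 2, 0, 1, 1, 0 and 0, and with fry 6, 11, 13, 7, 2 and 9. In settings other than leaving out a library or the block, lost calls, counted once per named gene and setting, numbered 44 in males, 10 in females, 16 for the average, 21 for the interaction, 14 for sex in solvent and 18 for sex in EE2. At this depth and size the interaction recovered 6.33% of simulated changes of 0.5, so small differences between the sexes were mostly not detectable.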

Other observations

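Interferon-response genes were high in 4 embryos of 3 groups. The mean log2 CPM of the interferon and inflammatory list was 4.84 in solvent male replicate 2, 4.06 in solvent male replicate 7, 4.61 in EE2 male replicate 3 and 3.60 in solvent female replicate 9, and between 2.49 and 3.29 in the other 16. RSAD2, an antiviral enzyme, stood at 73.5, 21.6, 36.6 and 2.5 CPM in these libraries. These libraries were picked by their values, so no test was made between them and the rest.

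Cardiac muscle transcripts were high in 2 EE2 males. EE2 male replicate 5 held 84.4 CPM of ACTC1 and 58.5 CPM of TNNT2, and EE2 male replicate 4 held 20 and 14.8 CPM, while the other 18 libraries held at most 8.13 and 3.39 CPM, both in EE2 female replicate 1. ACTA1 lay between 3.86 and 8.02 CPM in all 20 libraries.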
